A study of Mus musculus with 6 samples.

How the data were processed

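RNA from 6 samples of mouse Ba/F3-N cells was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, after biotin labelling with an amplification kit, per the labels' protocols. The samples fell into 2 groups of 3, taken from the sample titles: cells given 1 µM N-arachidonoyl dopamine (NADA) and cells given vehicle, both collected after 12 hours. No label gives a batch, a culture number or a scan date, so p-values measure the spread between these arrays, which may be technical only. For arrays, their number (3 per group) limits the precision.

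The deposited values are intensities on a linear scale, 1 value for each of 45101 probe sets on each array, and no detection calls stand beside them. MAS5 and RMA are named in the submitters' processing notes, with neither a version nor the role of each. The scale of the values was read from the values themselves, which ran from 2.19 to 20113 over the 6 arrays. The array medians of the deposited intensities were 38.92, 38.93 and 39.11 in the NADA samples and 37.95, 38.13 and 38.0 in the vehicle samples. These lie within 0.2 log2 of each other, so the values were treated as normalized by the authors and used as deposited after taking log2. A normalization of this kind sets the bulk of genes equal between arrays, so that a change shared by most transcripts is not visible in the fold changes.

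The 64 control probe sets were kept out of the gene tests. Of the other 45037 probe sets, 34945 were paired with 1 gene by the platform annotation, 932 with several genes and 9160 with none in the table used here, and only those with 1 gene were named. Gene identifiers of 34754 of them matched a RefSeq gene table of the GRCm38.p6 assembly, used for names only, and 0 symbols changed. Probe sets with a mean intensity under 38.64, the median of all probe sets, were left out as dim. Of the 22519 that passed, 18979 had 1 gene, and the brightest was kept per gene, which left 10526 genes. Among 4858 genes with several passing probe sets, 241 had probe sets called in both directions. Probe sets of the types x and s can bind several transcripts, which applies to those of Rrm2, Mcm2, Aurkb, Nop56, Nhp2, Gstm1, Tnfaip2, Ndufab1, Abhd4, Cad, Shmt2, Trib3 and Ifna1.

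NADA was compared with vehicle by limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, two-sided, with group as the only term, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The words rose and fell are used for called genes. The ± beside a log2 fold change is the standard error of the fit over 3 arrays per group. The 33 gene lists were tested with limma's camera at the preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes tested. Adjustment ran over the 32 lists with at least 5 tested members. Camera was repeated with a correlation estimated for each list, which is a severe test with 6 arrays, and fry was run, which asks whether the genes of a list moved on balance one way and compares them with no other genes. Counts of members were also taken with p-values adjusted over the list alone. Plots were drawn with matplotlib 3.10.9.

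The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule names the 12 highest and the 12 lowest log2 fold changes among called genes whose groups do not overlap, leaving out predicted gene models. It adds up to 4 members with the smallest p from each called list and from the lists of ERK pathway targets and of endocannabinoid, vanilloid and dopamine handling, and always Nras, Trpv1, Cnr1 and Cnr2. Any gene named outside this rule was chosen after its values were seen, as the text then says.

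Alternatives covered quantile normalization, median centring, adding 32 before log2, a floor of 50 before log2, no dim filter, a filter at the 70th percentile, no intensity trend, array weights, other ways of joining probe sets, a minimum of 1.5-fold, an adjusted p under 0.01, the replicate number as a block, and leaving out each array. Scaling each array to its bacterial poly-A control RNAs was added after seeing the data. The steps were tested on simulated data with the same 10526 genes and 200 changed genes, 50 at each size. Of these, 46% were recovered at 1.2-fold, 86% at 1.3-fold, 92% at 1.5-fold and 100% at 2-fold. Among the 168 calls 3.57% were false. In a separate simulation, with the autophagy and lysosome list alone shifted, that list was the only 1 of 32 called. Both simulations drew genes independently and held no labelling difference between groups, and far fewer genes changed than the 7719 called in the data. The correlation estimated in the data reached 0.25 for a called list, so the error of list calls with correlated genes was not tested.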

Results

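Ba/F3-N is a line of mouse bone marrow origin made from Ba/F3, a pro-B cell line that ordinarily needs interleukin-3 to grow, by introducing the oncogenic G12D form of NRAS, a small GTPase that signals to the RAF-MEK-ERK and PI3K-AKT pathways. NADA is a conjugate of arachidonic acid and dopamine that acts on the vanilloid receptor TRPV1 and on cannabinoid receptors. Transcript levels were measured in 3 samples exposed to 1 µM NADA for 12 hours and in 3 vehicle samples. The comparison of these groups asks which transcripts in NRAS-driven cells differ after NADA. Arrays of 1 group correlated across genes at 0.9972 to 0.9984 and arrays of different groups at 0.9361 to 0.9395, and the median SD of a gene between arrays of a group was 0.064 on the log2 scale.

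Relative to the bulk of genes, NADA-treated cells had higher mRNA levels of antiviral genes and lower levels of genes for ribosome production and DNA replication. With the values as deposited, Tmem140, an interferon-inducible membrane protein gene, had the highest log2 fold change (4.36 ± 0.09), followed by Oasl2 (4.2 ± 0.08), Isg20 (4.09 ± 0.10) and Ifit1 (3.98 ± 0.12), all induced by interferon. Rhag, a component of the red cell Rh complex, rose by 3.68 ± 0.08, Pik3ip1, an inhibitor of PI3K, by 3.23, Oas2 by 3.21, the aldehyde oxidase gene Aox1 by 3.20, Trp53inp1 by 3.07, Oasl1 by 3.05, Xaf1 by 3.0 and Bpifc by 2.94. Gem, a small GTPase of the RGK family, had the lowest log2 fold change, -3.95 ± 0.08. It was followed by the matrix metalloproteinase Mmp9 (-2.90 ± 0.06), the ETS factor Etv5 (-2.65 ± 0.07), the ribosome assembly factor Rrp12 (-2.55) and the uracil-DNA glycosylase Ung (-2.55). Fry (-2.54), cyclin E2 (Ccne2, -2.53), Ccnb1ip1 (-2.47), thymidine kinase (Tk1, -2.41), the zinc and iron transporter Slc39a14 (-2.41), Tuba8 (-2.40) and spermidine synthase (Srm, -2.39) fell as well.

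Of 10526 genes tested, 7719 (73.3%) were called by limma, 3768 higher and 3951 lower in NADA, and 1143 of them differed at least 2-fold, 512 higher and 631 lower. The 3 NADA values of 7986 genes (75.9%) did not overlap the 3 vehicle values, against 10% by chance. Scaled to the bacterial poly-A control RNAs, an alternative chosen after seeing the data, the median of all genes moved to -0.57 and the split became 733 higher and 8009 lower. In vehicle, Tmem140, Oasl2, Ifit1, Rhag and Bpifc lay below the intensity of 38.64 used as the dim limit, and with a floor of 50 their log2 fold changes were 2.87, 1.92, 2.05, 1.74 and 2.14. With 32 added before log2, those of Isg20 and Gem were 3.49 and -3.32, and Isg20 then ranked above Tmem140 (3.0) and Oasl2 (2.38), so the order among these genes depends on how low values are treated. With all probe sets of a gene averaged, the log2 fold changes of Trp53inp1 and Slc39a14 were 2.26 and -1.74.

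**Figure D1:**
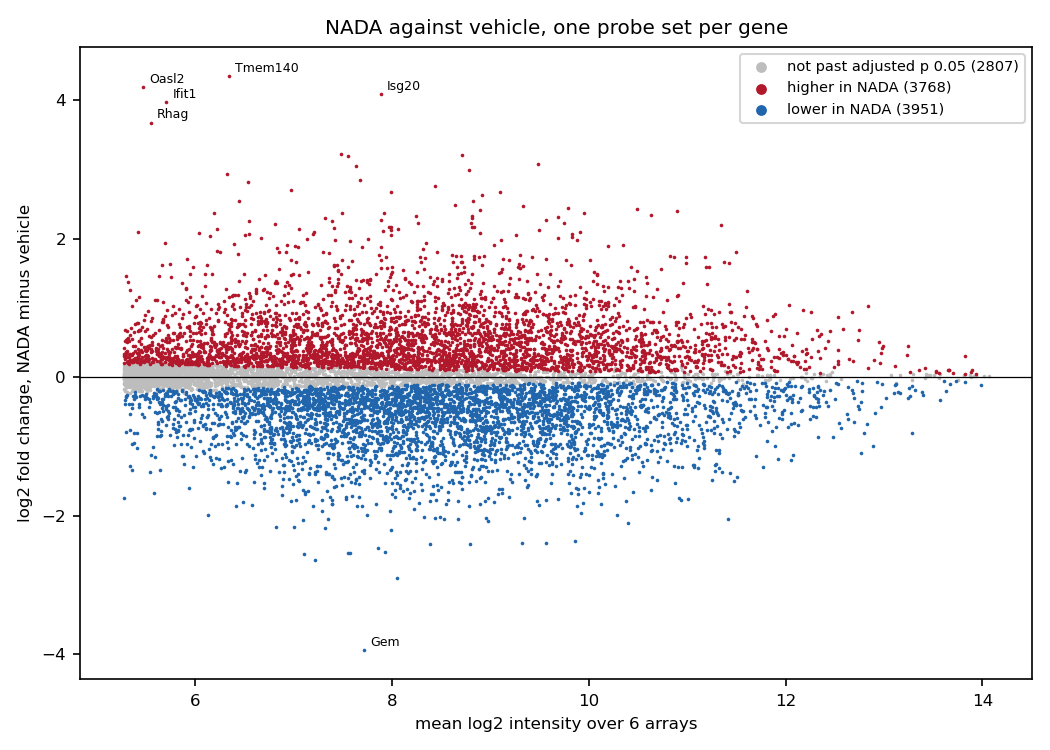
Log2 fold change (NADA minus vehicle, vertical) against mean log2 intensity over the 6 arrays (horizontal) for 10526 genes, each point 1 gene. Red points are the 3768 genes called higher, blue the 3951 called lower and grey those not called, with the values as deposited; scaled to the poly-A controls the split is 733 to 8009.

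**Figure D2:**
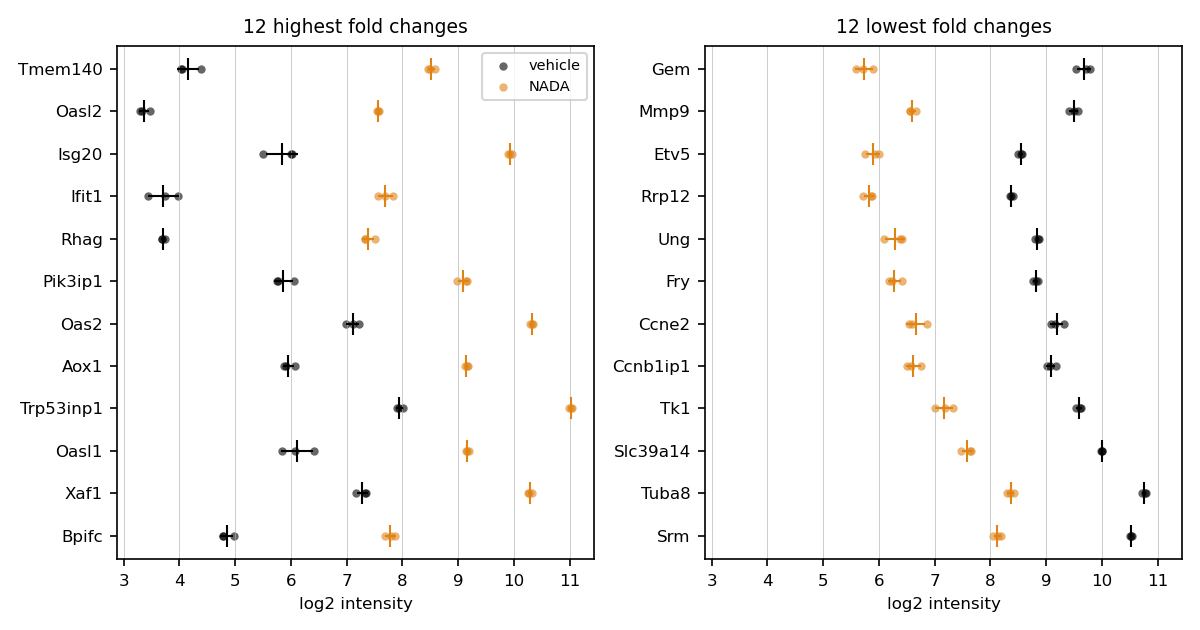
Log2 intensity (horizontal) of the genes with the 12 highest (left) and 12 lowest (right) log2 fold changes, on each of 3 NADA arrays (orange) and 3 vehicle arrays (black). Ticks are means and bars SDs (n = 3); the groups do not overlap for any of these genes.

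The arrays of the 2 groups also differed in their control probe sets. The bacterial poly-A RNAs, which are added to each RNA sample before labelling, had a mean log2 intensity of 8.72 ± 0.21 (SD, n = 3) in NADA and 8.14 ± 0.01 in vehicle, a 1.49-fold difference. The hybridization controls, added after labelling, stood at 10.08 ± 0.05 and 9.93 ± 0.10, a 1.11-fold difference. The log2 ratio of 3' to 5' probe sets of the actin gene Actb was 1.06 ± 0.05 in NADA and 0.67 ± 0.04 in vehicle, and its mean over the poly-A RNAs was 1.31 ± 0.02 and 1.08 ± 0.01. In each of these the groups did not overlap, and the two-sided exact permutation test gave 0.1, the smallest p that 3 against 3 arrays allow. These differences separate the same arrays as the treatment does, so any shift of a gene group described here comes together with them. Scaling to the poly-A RNAs lowers every log2 fold change by 0.58. Fold changes relative to other genes are the same under that scaling, so it cannot check the place of a list among the other genes.

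**Figure D3:**
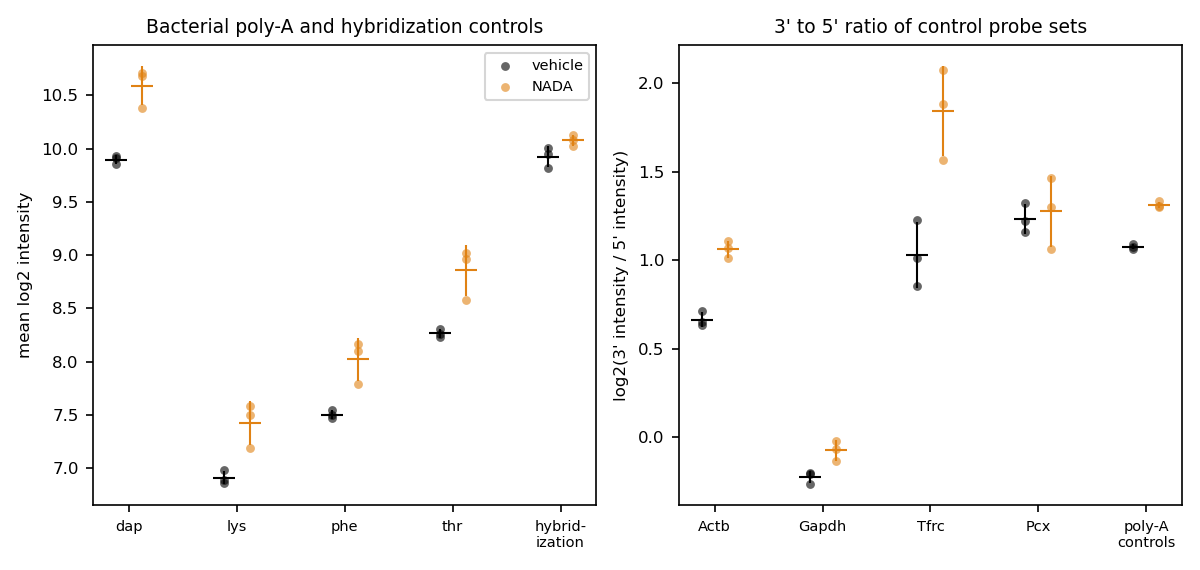
Left, mean log2 intensity of the 4 bacterial poly-A control RNAs and of the hybridization controls; right, log2 ratio of 3' to 5' intensity for 4 mouse genes and for the poly-A controls. Points are single arrays (NADA orange, vehicle black), horizontal ticks means and bars SDs (n = 3); only the Pcx ratio overlaps between the groups.

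Of the 32 lists tested, 14 differed from the other genes by camera, 9 upward and 5 downward. With an estimated correlation 2 calls held, those of the interferon-stimulated genes and of ribosome biogenesis. Counts of members adjusted over the list alone equalled those over all genes tested in every list except 3: autophagy and lysosome genes (39 rose, against 38), RAS genes (13 rose, against 12), and fibroblast, epithelial and endothelial markers (1 rose and 0 fell, against 2 and 1). Some genes stand in several lists, such as Sqstm1, Cdkn1a, Gadd45a, Ccng2 and Fabp5.

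Interferon-stimulated genes, which cells switch on in antiviral defence, were higher in NADA. Of 34 members named on the array 29 passed the dim filter, which uses the mean over all arrays. A member dim in vehicle could pass only through its NADA signal, as Oasl2 did (intensity 188.9 in NADA and 10.3 in vehicle). Members dim in both groups are not counted here. Of the 29 tested 28 rose, and 1, Ifit2, fell by 0.21 on the log2 scale, a gene chosen after its values were seen. The median log2 fold change was 1.82, and 1.25 after scaling to the poly-A RNAs (camera adjusted p = 1.06e-11, and adjusted p = 0.0409 with an estimated correlation). The 2'-5'-oligoadenylate synthetase genes Oas2 (intensity 1276 in NADA and 137.9 in vehicle), Oasl2 and Oas1a (log2 fold change 1.89 ± 0.04) and the XIAP-associated factor Xaf1 had the smallest p. NF-kB and inflammatory targets also moved upward, with 18 of 24 higher and 2 lower (median 0.62, adjusted p = 4.70e-04; adjusted p = 0.106 with an estimated correlation). The cytokine Il6 rose by 2.17 ± 0.08, Tnfaip2 by 1.70 ± 0.05 and the NF-kB inhibitor Nfkbia by 0.72 ± 0.04, whereas the manganese superoxide dismutase Sod2 fell by 0.61 on the log2 scale. After scaling to the poly-A RNAs the NF-kB median was 0.04, and Nfkbia was no longer called (0.14, adjusted p = 0.3).

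Genes of ribosome production were lower in NADA. All 56 measured members of the list of ribosome biogenesis and MYC targets fell, with a median log2 fold change of -1.23 (camera adjusted p = 3.51e-20, and adjusted p = 0.0495 with an estimated correlation). Nucleolar phosphoprotein Nolc1 changed by -2.37 ± 0.04, Srm by -2.39 ± 0.04, and the small nucleolar ribonucleoprotein genes Nop56 and Nhp2 by -1.77 ± 0.03 and -1.44 ± 0.03. Among subunits of oxidative phosphorylation 43 of 49 fell and 2 rose, with a median of -0.25 (adjusted p = 1.21e-07; adjusted p = 0.106 with an estimated correlation). Cyc1 (-0.96), Atp5g1 (-0.87), Ndufb10 (-0.85) and Ndufab1 (-0.73) were the members with the smallest p. Both medians were lower still after scaling to the poly-A RNAs, at -1.81 and -0.82.

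Proliferation genes were lower in NADA, more so for DNA replication than for mitosis in the size of the medians, a difference that was not tested. Of 50 DNA replication and G1/S genes 49 fell and 1 was not called, with a median of -1.07 and of -1.65 after scaling to the poly-A RNAs (adjusted p = 4.00e-17; adjusted p = 0.111 with an estimated correlation). Uhrf1, which maintains DNA methylation, changed by -1.99 ± 0.03, the replication fork protein Tipin by -1.78 ± 0.03, the ribonucleotide reductase subunit Rrm2 by -1.76 ± 0.03 and the replicative helicase subunit Mcm2 by -1.44 ± 0.04. Of 61 mitosis and G2/M genes 48 fell and 6 rose, with a median of -0.31 and of -0.88 after that scaling (adjusted p = 1.50e-05; adjusted p = 0.358 with an estimated correlation), among them Mybl2 (-2.17), Aurkb (-1.13), Cdk1 (-0.98) and Ube2c (-0.63).

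As a list, genes that restrain the cell cycle moved the other way with the values as deposited. Of 16 cell cycle inhibitors and quiescence genes 11 rose and 4 fell, with a median of 0.53. Camera gave an adjusted p = 0.0144, and an adjusted p = 0.188 with an estimated correlation. After scaling to the poly-A RNAs the median turned to -0.05. The list keeps its place above the other genes by construction, and camera still called it (adjusted p = 0.00108). Cyclin G2 (Ccng2) rose by 2.18 ± 0.05, Klf6 by 2.02 ± 0.06, Tob1 by 1.41 ± 0.06 and the CDK inhibitor Cdkn1a by 1.12 ± 0.04. The 4 that fell, named after their values were seen, were Rbl1 (-0.82) and the CDK inhibitors Cdkn2d (-0.59), Cdkn2b (-0.31) and Cdkn2c (-0.19). FOXO targets, which PI3K and AKT signalling holds down, included 15 that rose among 16 and 0 that fell (median 0.92, adjusted p = 4.62e-06; adjusted p = 0.107 with an estimated correlation; 0.34 after that scaling). Pik3ip1, Ccng2, the stress gene Gadd45a (2.33 ± 0.07) and the mitophagy receptor Bnip3 (1.5 ± 0.05) led that list. Among p53 targets 15 of 25 rose and 6 fell, with a median of 0.37. Camera gave an adjusted p = 0.0357, and an adjusted p = 0.358 with an estimated correlation. After the scaling the median turned to -0.21, with the place above the other genes again kept by construction (camera adjusted p = 0.00383). Trp53inp1, Gadd45a, Cdkn1a and the death receptor Fas (2.37 ± 0.08, and 1.73 with a floor of 50) had the smallest p among the p53 targets.

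Genes of the unfolded protein response, autophagy and the oxidative stress response were higher as lists with the values as deposited, while the heat shock and integrated stress response lists were not called. In the unfolded protein response of the endoplasmic reticulum 30 of 31 genes rose and 1 fell (median 0.80, adjusted p = 2.05e-11; adjusted p = 0.136 with an estimated correlation), and the median was 0.22 after scaling to the poly-A RNAs. The COPII coat gene Sec24d rose by 2.23 ± 0.04, the degradation factor Herpud1 by 2.03 ± 0.04, Dnajb9 by 1.71 ± 0.04 and the chaperone BiP (Hspa5) by 1.03 ± 0.03. Of 45 autophagy and lysosome genes 38 rose and 3 fell (median 0.64, adjusted p = 5.11e-10; adjusted p = 0.106 with an estimated correlation), with a median of 0.06 after the scaling. The autophagy receptors Sqstm1 and Nbr1 rose by 2.41 ± 0.03 and 1.52 ± 0.04, cathepsin D (Ctsd) by 1.29 ± 0.04 and the autophagosome protein Map1lc3b by 1.25 ± 0.04. Of 32 NRF2 and oxidative stress genes 22 rose and 7 fell, with a median of 0.48. Camera gave an adjusted p = 0.00117, and an adjusted p = 0.106 with an estimated correlation. Here the median turned to -0.10 after the scaling, with the place above the other genes kept by construction (camera adjusted p = 2.26e-05). Heme oxygenase (Hmox1, 2.27 ± 0.06), the glutathione transferase Gstm1 (2.12 ± 0.06) and biliverdin reductase (Blvrb, 1.51 ± 0.04) rose beside Sqstm1.

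Of 21 genes of cholesterol synthesis and SREBP2 targets 13 fell and 4 rose (median -0.44, adjusted p = 0.0308; adjusted p = 0.579 with an estimated correlation), including Idi1 (-1.83), squalene epoxidase (Sqle, -1.35), Fdps (-1.0) and Msmo1 (-0.88). The call was lost without NADA replicate 3 (-0.41, adjusted p = 0.0533) and with a dim filter at the 70th percentile (-0.50, adjusted p = 0.0588). Of 21 PPAR targets and fatty acid oxidation genes 14 rose and 4 fell (median 0.33, adjusted p = 0.0256; adjusted p = 0.539 with an estimated correlation). The lipid droplet proteins Plin3 (1.76) and Plin2 (1.31) and the carnitine palmitoyltransferase Cpt1a (1.15) rose, and the fatty acid carrier Fabp5 fell by 1.96 on the log2 scale. After scaling to the poly-A RNAs the cholesterol median was -1.02, and the PPAR median turned to -0.25 and the list was not called (adjusted p = 0.125).

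**Figure D4:**
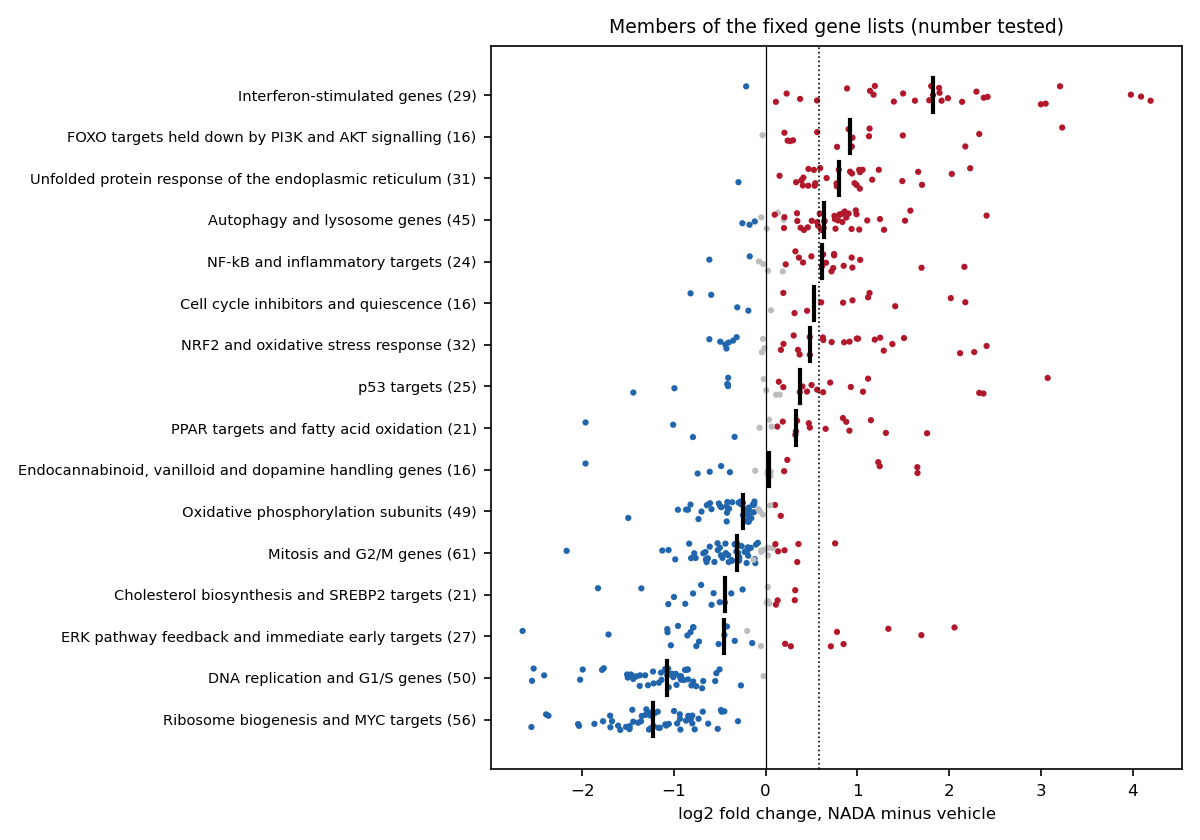
Log2 fold change (NADA minus vehicle, horizontal) of each member of the 14 called gene lists and of the ERK and endocannabinoid lists, with the number of members tested in brackets; red rose, blue fell, grey not called, black bars medians, and height within a row has no meaning. The dotted line is the poly-A control difference of 0.58: medians between 0 and that line (cell cycle inhibitors, NRF2, p53, PPAR and the uncalled endocannabinoid list) lie below 0 after scaling to those controls.

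Genes tied to RAS signalling and to the targets of NADA moved in both directions. Among 27 ERK pathway feedback and immediate early targets 17 fell and 8 rose. The list was not called by camera (median -0.45, and -1.03 after scaling to the poly-A RNAs, adjusted p = 0.0713), although it was with no dim filter (-0.38, adjusted p = 0.0184). With an estimated correlation camera gave an adjusted p = 0.226. Fry, which called 29 of the 32 lists and compares with no other genes, called it too (adjusted p = 1.10e-05). Etv5 and cyclin D1 (Ccnd1, -1.71 ± 0.06) fell, whereas Phlda1 (2.06 ± 0.08) and Jun (1.70 ± 0.06) rose. RAS genes, their processing enzymes and effectors split into 12 that rose and 12 that fell among 31 (median 0.06, mean -0.02, and median -0.51 after that scaling, adjusted p = 0.999). Nras fell by 0.39 on the log2 scale (intensity 489 in NADA and 642 in vehicle, adjusted p = 3.52e-07), and both other probe sets of the gene were also lower. Whether these probe sets detect the introduced NRAS, the endogenous gene or both is not given in the sources used here.

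Among 16 genes of endocannabinoid, vanilloid and dopamine handling 6 rose and 5 fell (median 0.04, and -0.54 after scaling to the poly-A RNAs, adjusted p = 0.658). The monoamine transporter Slc18a2 rose by 1.66 ± 0.03, Abhd4, an enzyme of N-acylethanolamine synthesis, by 1.65 ± 0.03 and the channel Trpv2 by 1.24 ± 0.05, while Fabp5 fell. The cannabinoid receptor gene Cnr2 rose by 1.23 ± 0.06 (intensity 163 in NADA and 69.4 in vehicle). The probe sets of Trpv1 (6.77 and 6.96) and of Cnr1 (36.9 and 38.3, and 4.72 and 4.86) were dim in both groups and did not enter the test. Without the dim filter their adjusted p were 0.789, 0.696 and 0.807.

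The remaining lists were not called with the values as deposited, and after scaling to the poly-A RNAs their medians all lay between -0.80 and -0.30 except those of the histone genes (0.73) and of the untested aryl hydrocarbon receptor targets (0.03). IL-3 receptor and STAT5 targets had 10 of 18 higher and 5 lower (median 0.16, adjusted p = 0.214), apoptosis regulators 14 of 25 higher and 8 lower (median 0.11, mean -0.01, adjusted p = 0.586), and targets of the integrated stress response 18 of 38 higher and 16 lower (median 0.04, adjusted p = 0.741). Heat shock genes had 7 of 17 higher and 8 lower (median -0.03, mean 0.14, adjusted p = 0.977). Fatty acid synthesis genes had 10 of 22 higher and 9 lower (median -0.04, mean 0.07, adjusted p = 0.901), glycolysis and hypoxia targets 10 of 28 higher and 15 lower (median -0.23, adjusted p = 0.359), and metal and iron handling genes 6 of 13 higher and 6 lower (median -0.11, adjusted p = 0.744). Splicing and fast-turnover RNAs had 15 of 32 higher and 14 lower (median 0.01, adjusted p = 0.716), and histone genes 4 of 7 higher and 2 lower (median 1.31, adjusted p = 0.207), a list that was called after that scaling (0.73, adjusted p = 4.68e-04). Of the 9 aryl hydrocarbon receptor targets named on the array only 4 passed the dim filter, too few for the list test, and 3 of them rose.

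Markers of blood cell types and of other cells that a culture might hold were not called as lists either. B lymphoid markers had 3 of 10 higher and 1 lower (median 0.01, adjusted p = 0.716), myeloid, mast cell and progenitor markers 7 of 15 higher and 6 lower (median 0.09, adjusted p = 0.658), and erythroid and megakaryocyte markers, with Rhag among them, 6 of 13 higher and 3 lower (median 0.19, adjusted p = 0.473). T cell and natural killer markers had 2 of 6 higher and 1 lower (median -0.02, adjusted p = 0.901). Fibroblast, epithelial and endothelial markers had 2 of 7 higher and 1 lower (median -0.04, mean 0.08, adjusted p = 0.744). Surface receptors and adhesion molecules of hematopoietic cells had 13 of 21 higher and 6 lower (median 0.28, adjusted p = 0.0713).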

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

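All tests reported in this part were chosen after the results were seen. The values concern control probe sets that the gene comparison did not use. All but the Pcx ratio and the absent control TrpnX were higher in every NADA array than in every vehicle array. TrpnX overlapped between the groups, with a log2 difference of -0.06 (NADA minus vehicle). Groups of 3 arrays were not tested for outliers.

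The poly-A control RNAs were higher in NADA by 0.58 on the log2 scale, with NADA replicate 3 the lowest of its group at 8.486 and vehicle at 8.14 ± 0.01, and the hybridization controls were higher by 0.15. A brightness or hybridization difference between arrays as the whole cause is spoken against by the poly-A controls minus the hybridization controls, which still differed by 0.43 (-1.36 ± 0.17 in NADA, -1.78 ± 0.08 in vehicle). The authors' normalization was weighed with the bacterial RNA dap, whose mean log2 intensity in vehicle (9.90) was near that of the hybridization controls (9.93). Dap minus those controls was higher by 0.54 in NADA (0.51 ± 0.14) than in vehicle (-0.03 ± 0.12). This speaks against a normalization that moves both classes alike as the whole cause. Intensities of single probe sets were not compared, so a normalization that depends on intensity is not excluded. Less mRNA per unit of total RNA in NADA cells, or more control RNA added to those samples, would raise all 4 bacterial RNAs by a like amount, and their differences lay within 0.18 of each other. The differences ran from 0.51 (lys) to 0.69 (dap), and the bound for a like amount was the SD between NADA arrays, 0.21. NADA replicate 3 was the lowest of its group for all 4 RNAs, which widens that bound without measuring scatter between the RNAs. Staying within it is therefore weak support. Whether either of the pair holds is not decided by these data, since no amount of control RNA or of RNA per cell is given in the sources used here. Whether a labelling or amplification difference contributes to the level of these RNAs was not tested.

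The log2 ratio of 3' to 5' probe sets was higher in NADA by 0.40 for Actb, 0.15 for Gapdh and 0.81 for Tfrc, while that of Pcx overlapped between the groups. Degradation of the cells' RNA as the whole cause would leave the bacterial RNAs alone, since they are added after extraction, yet their mean ratio was higher by 0.24. A labelling or amplification difference between the groups may contribute, because the ratio of all 4 bacterial RNAs was higher in every NADA array. A biological part of the mouse ratios was not tested.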

How the results depend on the processing

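Scaling to the poly-A controls was chosen after seeing the data; the other alternatives were fixed before. For 78 named genes, 1550 of 1552 alternative values kept their direction and call, 0 reversed, and 2 lost the call: Nras at a minimum of 1.5-fold (-0.39) and Nfkbia scaled to the poly-A controls (0.14). The 7719 calls became 3031 at a minimum of 1.5-fold, 1369 higher and 1662 lower, and scaling to the poly-A controls gave 733 higher and 8009 lower. Other settings gave 6309 (of 7432 genes, filter at the 70th percentile) to 8230 (of 18193, no filter), and leaving out 1 array 7364 to 7735. The 14 lists became 2 with an estimated correlation and 29 by fry, and 13 or 14 without 1 array. Over 478 alternative list values 443 kept direction and call, 14 lost a call, 16 gained one and 5 reversed. Under fry the RAS genes (median 0.06) were called as moving downward, as their mean does (adjusted p = 0.00348). Scaling to the poly-A controls, which subtracts the control difference from every gene, turned the medians of cell cycle inhibitors (-0.05), p53 targets (-0.21), NRF2 targets (-0.10) and PPAR targets (-0.25) by construction. By camera the first 3 kept their call and PPAR lost it (adjusted p = 0.125), while histone genes gained one (0.73). Fold changes relative to other genes are the same under this scaling, so a kept, lost or gained call is no check on them. The cause of the other list changes was not tested. The replicate block gave 7742 genes and 14 lists and changed no call of a named gene or list. Deviations of same-numbered arrays correlated at 0.16, -0.10 and 0.02, so the numbers were not taken to pair the samples; NADA replicate 1 correlated best with vehicle 1, but replicates 2 and 3 did not correlate best with their own number. Dim signal limits the folds of genes near background in 1 group.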

Other observations

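The gene families and the extra genes in this part were chosen after the data were seen, as was the test of a labelling difference for the interferon genes; the test of interferon transcripts and the counts over other groupings were fixed before.

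Several further gene families were lower in NADA; as they were chosen on these data, their p-values describe them and are no independent evidence. Some members also stand in fixed lists: Timm10, Polr1a, Polr1b, Polr1c, Cad, Ppat and Nme1 in that of ribosome biogenesis, Rrm1, Rrm2 and Tyms in that of DNA replication, and most of the synthetases and several serine enzymes in that of the integrated stress response. Mitochondrial ribosomal protein genes fell in 66 of 76 cases and rose in 3 (median -0.58, camera adjusted p = 1.44e-11; adjusted p = 0.0742 with an estimated correlation), led by Mrpl12 (-1.76) and Mrpl20 (-1.43), whereas cytosolic ribosomal protein genes were not called as a family (15 higher and 9 lower of 41, median 0.04 and -0.54 after scaling to the poly-A controls, adjusted p = 0.481). All 10 RNA exosome genes fell (median -1.03, adjusted p = 1.66e-05), as did 18 of 19 nucleoporin genes (median -0.70, adjusted p = 8.58e-07), 17 of 21 genes of mitochondrial protein import (median -0.66, adjusted p = 1.09e-05) and 22 of 25 RNA polymerase subunit genes (median -0.45, adjusted p = 1.14e-05), each with an adjusted p = 0.0742 with an estimated correlation. Purine and pyrimidine synthesis fell in 20 of 22 genes (median -1.10, adjusted p = 9.13e-08; adjusted p = 0.0742 with an estimated correlation), with Ctps at -2.08 and Cad, which starts pyrimidine synthesis, at -2.04. Serine and folate one-carbon enzymes fell in 8 of 10 (median -1.33, adjusted p = 5.21e-04; adjusted p = 0.146 with an estimated correlation), and cytosolic aminoacyl-tRNA synthetases in 14 of 19 (median -0.50, adjusted p = 0.00155; adjusted p = 0.101 with an estimated correlation).

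Within the integrated stress response list, which was not called, the stress regulators Ddit3 (2.67) and Trib3 (2.32) rose. Its enzymes Mthfd2 (-1.58), Shmt2 (-1.40) and Psat1 (-1.21) fell, and the serine enzyme Psph was not called (-0.10, adjusted p = 0.19). The closely related receptor subunit genes Csf2rb2 and Csf2rb, through which interleukin-3 signals, rose by 2.35 and 1.75. Vacuolar ATPase genes, of which Atp6v0d1, Atp6v1a and Atp6v1h also stand in the autophagy and lysosome list, rose in 11 of 13 cases (median 0.53, adjusted p = 8.14e-05; adjusted p = 0.0742 with an estimated correlation) and annexins in 7 of 8 (median 0.57, adjusted p = 5.50e-04; adjusted p = 0.0742 with an estimated correlation), but scaled to the poly-A controls these medians were -0.05 and -0.01. Proteasome genes, with Psmb8 and Psmb9 also in the interferon list, had 23 of 38 higher and 7 lower (median 0.12, adjusted p = 0.0197; adjusted p = 0.121 with an estimated correlation), and their median was -0.45 after that scaling. The 3 YPEL genes tested, Ypel3 (2.55), Ypel5 (2.30) and Ypel2 (1.97), all rose.

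The rise of interferon-stimulated genes was weighed against 2 explanations. A labelling or scaling difference that moves genes of like intensity alike is spoken against by 10000 sets of genes matched on intensity. Of these sets 0 reached the median of 1.82 and the highest was 0.43. The sets come from the same arrays, were matched on intensity only and, like camera, compare the list with other genes. A labelling difference that depends on the transcript, such as the 3' bias, was therefore not tested. Transcription of interferon genes by the treated cells is a hypothesis that was not decided. Among 9 probe sets of the Ifna, Ifnb1 and Ifng genes named in advance, the highest log2 fold change was 0.42 (Ifna1, adjusted p = 0.00102), below the 0.5 set beforehand. It came from a probe set that can bind several transcripts. Ifnb1 stood at 0.10 (adjusted p = 0.545), and only 1 of the 9 was above the median intensity. The set named in advance also held Ifne, Ifnk and the Ifnl genes, which had no probe set paired with 1 gene and were not assessed. Ifnz, a type I interferon gene outside that set, rose by 1.04 (intensity 1250 in NADA and 609 in vehicle, adjusted p = 5.16e-10); it was counted in a first run of the test, where it met the bound, and was taken out when its absence from the genes named in advance was noticed.

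The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 7719 genes and the highest of the others 0; for gene lists these were 14 and 11. Each of the other groupings still sets a majority of NADA arrays against a majority of vehicle arrays.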
